A study of Homo sapiens with 12 samples.

How the data were processed

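RNA sequencing measured transcript levels in HT29 cells, a line from a human colorectal adenocarcinoma, that express the Cas9 nuclease. Per the labels' protocols, cells were transduced with lentivirus carrying either a non-targeting guide RNA (WT) or a guide against QRICH1 (QRICH1 KO), and were then given the solvent DMSO or tunicamycin (Tm) at 0.3 µg/ml for 14 h. Tunicamycin blocks the first step of N-linked glycosylation, so that unfolded proteins accumulate in the endoplasmic reticulum (ER). The 12 libraries form 4 groups of 3 (WT DMSO, WT Tm, QRICH1 KO DMSO and QRICH1 KO Tm), taken from the sample titles, and the series design text calls the 3 libraries of a group biological replicates. Per the labels' protocols, RNA was converted to cDNA by a modified Smart-seq2 method, which copies polyadenylated transcripts, and libraries were made by Nextera XT tagmentation for an Illumina NextSeq. This chemistry does not mark the strand of a transcript and adds no molecular identifiers.

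The authors deposited 1 table of whole-number read counts per gene, unnormalised, with 20015 genes and 1 column for each library. No column belonged to a sample of another series. Per the submitters' processing notes, Trimmomatic, STAR, DESeq2 and the human genome build hg38 were used, without versions or roles. The counting tool, its strand setting, its treatment of reads that map to several places and the annotation release are not given in the sources used here. Gene IDs carried Ensembl versions. With the version removed, 19972 of them matched GENCODE release 29, from which hg38 positions were taken, and 19893 matched a table of current gene symbols. The table holds almost only protein-coding genes (19957), so levels are relative to protein-coding transcripts. Symbols were shared by 57 genes, and these were kept apart by ID.

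Total counts were 7529171, 15131238 and 12089615 in WT DMSO libraries 1 to 3, 12395549, 14250070 and 6856736 in WT Tm, 17861844, 14097141 and 14284543 in QRICH1 KO DMSO, and 13205487, 9063303 and 12334129 in QRICH1 KO Tm. At these totals 3 counts, the limit that a count of 0 allows, correspond to between 0.168 and 0.438 counts per 1000000 counts (CPM). This limit covers counting error only, since PCR copies are not independent molecules. Libraries of a group were compared in pairs over genes with at least 50 counts. The chi-square statistic per degree of freedom was 8.64 to 35.8, far above sampling noise in every pair, so no library was a copy of another in its group.

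Counts were scaled with TMM factors and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which left 11323 genes. A quasi-likelihood model with 4 group means was fitted to all 12 libraries, so that the groups share 1 estimate of the spread (common biological coefficient of variation 0.155). The tests were Tm against DMSO in WT, Tm against DMSO in QRICH1 KO, QRICH1 KO against WT under Tm, QRICH1 KO against WT under DMSO, and the interaction, which is the Tm response in QRICH1 KO less the Tm response in WT. Adjusted p-values of genes are two-sided edgeR quasi-likelihood values with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. The SE of a log2 fold change was taken from the quasi-likelihood F statistic. CPM values are TMM-scaled and given as mean ± SD over the 3 libraries of a group.

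The gene lists, written from textbook knowledge, held 803 genes in 29 lists, of which 1 (GPX1) had no entry in the table. They cover ATF4 and CHOP targets, aminoacyl-tRNA synthetases, amino acid transporters, ER chaperones, ER-associated degradation (ERAD), transducers of the unfolded protein response, ER translocation, N-glycosylation, ER-Golgi transport, ribosomal proteins, translation factors, ribosome biogenesis, apoptosis, the cell cycle, cholesterol synthesis, NF-kB targets, the interferon response, absorptive and secretory epithelial markers, markers of non-epithelial cells, mitochondrially encoded genes, p53 targets, neighbours of QRICH1, autophagy, heat shock proteins, NRF2 targets, immediate early genes, glycolysis and hypoxia, and nuclear-encoded oxidative phosphorylation. Each list with at least 3 tested members was compared with all other genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a comparison. Adjusted p-values of lists are these camera values. Camera was also run with the correlation estimated per list, and fry tested whether a list's genes moved, on balance, in 1 direction. Some genes belong to more than 1 list.

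Genes named in the text were QRICH1, a panel of stress genes (HSPA5, HSP90B1, DNAJB9, SDF2L1, HERPUD1, XBP1, ATF4, ATF3, DDIT3, TRIB3, CHAC1 and ASNS), the 10 genes with the largest log2 fold change in each direction among called genes with a mean CPM of at least 10 and all 3 libraries of one group above all 3 of the other, and up to 4 members of each list with the smallest p. Not every gene this rule allows is named. Genes outside it are said to be chosen after their values were seen. The design, the tests, the lists, this rule and the alternatives were set before the data were examined, with the exceptions stated beside the results.

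The alternatives were RLE scaling in edgeR, no low-count filter (17864 genes), a filter of at least 5 CPM in at least 3 libraries (8862 genes), DESeq2 1.42.0, limma voom with sample quality weights, the replicate number as an additive block, a fit to only the 6 libraries of a comparison, and leaving out each library in turn. In the last 2 the genes tested were kept as those of all 12 libraries, a decision made after a version that filtered anew had been seen. Leaving out both QRICH1 KO libraries numbered 3 together was an alternative chosen after seeing the data. The workflow was tested on simulated counts of 11189 genes with known changes. It recovered, for Tm against DMSO in WT, 24.2% of genes changed 1.5-fold, 71.6% of those changed 2-fold and 95.4% of those changed 4-fold, and 7.4% of its calls were false. Far fewer genes were changed there than by Tm in the data, with 136 calls against 2690. The adjustment is stricter with few changes, so these shares do not give the power of the real Tm comparison. For QRICH1 KO against WT under Tm the shares recovered were 33.6%, 69.2% and 90.9%, and 5.1% of calls were false. For the interaction they were 1.5%, 36.4% and 77.3%, and 4.9% of calls were false.

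Reads were not analysed here. Splicing, the guide sequence and edits at the QRICH1 locus were not analysed here, so the share of cells that carry an edit is not known. Because strand is not marked, reads of overlapping genes on opposite strands cannot be told apart.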

Results

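Gene expression was measured in 12 libraries of Cas9-expressing HT29 cells, with 3 libraries for each of the WT DMSO, WT Tm, QRICH1 KO DMSO and QRICH1 KO Tm groups. QRICH1 encodes a glutamine-rich protein with a caspase recruitment domain, and the series asks how it shapes the transcriptional response to ER stress. Total counts ranged from 6856736 to 17861844 per library. Tm and DMSO libraries were separated along the first principal component, which held 41.9% of the variance. On it the DMSO libraries of both genotypes lay between -33.03 and -25.21, the QRICH1 KO Tm libraries between 19.82 and 23.53 and the WT Tm libraries between 34.89 and 38.02. Most libraries had counts for 13124 to 14094 genes, whereas library 3 of QRICH1 KO DMSO had 15340 and library 3 of QRICH1 KO Tm had 14813. Mitochondrially encoded genes took 2.06% to 3.74% of the counts, and the keratin gene KRT8, which is typical of simple epithelia, was the most abundant gene with 3.33% to 5.82%. Of 24 markers of non-epithelial cells only LUM and CD14 passed the count filter, with a mean of at most 1.59 CPM (CD14), so this list was not tested.

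The targeted gene, QRICH1 (ENSG00000198218.11), lies at chromosome 3:49029707-49094363 (hg38, GENCODE 29). Its level was 22.72, 31.12 and 34.97 CPM in the WT DMSO libraries, 30.85, 31.05 and 25.69 in WT Tm, 23.34, 24.05 and 24.77 in QRICH1 KO DMSO, and 26.81, 22.36 and 19.17 in QRICH1 KO Tm. The group means were 29.6 ± 6.26, 29.2 ± 3.04, 24.1 ± 0.71 and 22.8 ± 3.84 CPM (SD, n = 3). No difference in QRICH1 mRNA between genotypes was called by the edgeR test, with a log2 fold change of -0.31 (SE 0.161, adjusted p = 0.577) under DMSO and -0.36 (SE 0.164, adjusted p = 0.352) under Tm. Nor was one called between Tm and DMSO, with -0.03 in WT (adjusted p = 0.939) and -0.08 in QRICH1 KO (adjusted p = 0.806). A Cas9 edit that shifts the reading frame need not lower the mRNA, so these levels are a weak check of the labels.

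**Figure D1:**
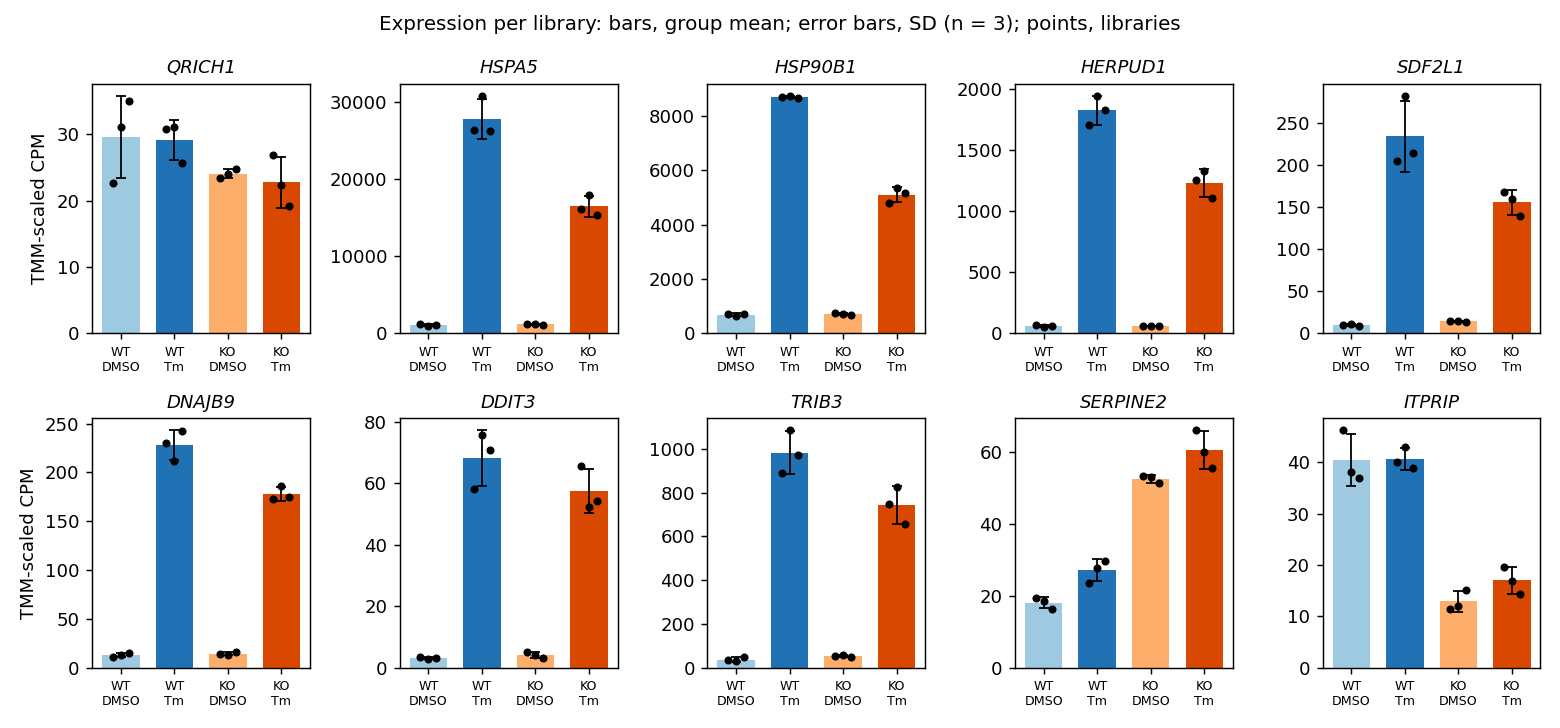
Levels of 10 genes in TMM-scaled CPM (y axis, starting at 0) in the 4 groups; bars are group means, error bars the SD (n = 3) and points the libraries. HSPA5 rose from 1080 to 27900 CPM with Tm in WT and from 1130 to 16500 CPM in QRICH1 KO, while QRICH1 itself stayed between 22.8 and 29.6 CPM.

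Tm against DMSO in WT asks what the ER stressor does in cells with intact QRICH1. Many genes of the unfolded protein response rose by more than an order of magnitude. HSPA5, which encodes the ER chaperone BiP, rose 25.8-fold (log2 4.69, SE 0.144, adjusted p = 8.26e-14), from 1080 ± 116 to 27900 ± 2630 CPM (SD, n = 3). HSP90B1, the ER paralog of HSP90, rose 12.8-fold (log2 3.68, SE 0.115), the co-chaperones DNAJB9 and SDF2L1 rose 17.5-fold and 23.4-fold, and HERPUD1, a component of ER-associated degradation, rose 31.7-fold (log2 4.99, SE 0.128, adjusted p = 1.31e-14). On the branch downstream of the kinase PERK, the transcription factor ATF4 rose 3.23-fold (SE 0.124 on the log2 scale), DDIT3, which encodes CHOP, rose 21.2-fold (log2 4.41, SE 0.185), and its targets TRIB3 and CHAC1 rose 25.9-fold and 25.6-fold. XBP1 and ATF3 rose less, by 2.15-fold (adjusted p = 3.27e-05) and 4.52-fold (adjusted p = 3.65e-05). ASNS was called as well, but its level of 0.156 CPM in WT DMSO and 1.71 CPM in WT Tm lies too near the detection limit for a fold.

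In all, 1431 genes were higher and 1259 lower with Tm in WT by the edgeR test, of which 536 and 257 changed at least 2-fold. All 3 libraries of one group lay above all 3 of the other in 1400 and 1205 of them, and in 37.5% of all genes tested, against 10% by chance. The largest increases among genes of at least 10 CPM, besides those above, were of AGR2, an ER protein disulfide isomerase, with 43.9-fold (log2 5.46, SE 0.158), NIBAN1 with 42.4-fold, the calcium-binding protein gene NUCB2 with 35.6-fold, the mTORC1 inhibitor gene DDIT4 with 28.3-fold and the trypsinogen gene PRSS1 with 23-fold. The largest decreases were smaller. EDN1, which encodes endothelin-1, was 3.89-fold lower (log2 -1.96, SE 0.22, adjusted p = 2.27e-06), the secreted antagonist gene SOSTDC1 3.76-fold, the WNT target LGR5 3.51-fold, FAM111B 3.1-fold and the tight junction gene CLDN2 3.07-fold, followed by DPYSL2, MYORG, TNS4, GINS2 and UHRF1 with 2.83-fold to 2.95-fold.

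All 5 lists of the ER protein folding and export machinery rose in WT with Tm. Of 28 ER chaperone genes 25 rose and 3 were not called, with a median log2 fold change of 2.15 (camera adjusted p = 9.74e-27), and 26 rose adjusted over the list alone. In ERAD 19 of 28 rose and 9 were not called (median 0.903, adjusted p = 1.86e-12), for example SELENOS 7.55-fold and ERLEC1 5.01-fold, and adjusted over the list alone 19 were higher and 1 lower. ER translocation had 22 of 25 higher and 3 not called by both adjustments, over all genes and adjusted over the list alone (median 1.42, adjusted p = 1.26e-20), with SRPRB, a subunit of the signal recognition particle receptor, at 6.04-fold and the channel gene SEC61A1 at 4.91-fold. N-glycosylation, the pathway that Tm blocks, had 23 higher, 1 lower and 12 not called of 36 (median 0.771, adjusted p = 1.62e-11), among them PGM3 5.22-fold and GFPT1 4.75-fold, 2 enzymes that make the sugar donor UDP-GlcNAc, and OSTC of the oligosaccharyltransferase 5.32-fold. Adjusted over the list alone it had 24 higher and 2 lower. In ER-Golgi transport 38 of 42 rose and 4 were not called by both adjustments, over all genes and adjusted over the list alone (median 1.19, adjusted p = 2.93e-26), including the COPII coat gene SEC24D 15.5-fold and ARFGAP3 5.84-fold. Transducers of the unfolded protein response rose in 7 of 12 with 5 not called by both adjustments, over all genes and adjusted over the list alone (median 1.18, adjusted p = 0.000145), such as CREB3L2 3.52-fold and ATF6 2.64-fold. These 6 calls held with an estimated correlation.

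Genes of amino acid supply rose too. Of 26 ATF4 and CHOP targets 22 rose and 4 were not called (median 2.28, adjusted p = 2.62e-22), with 23 adjusted over the list alone. Examples are the stress-induced SESN2 with 11.6-fold and the serine synthesis gene PSAT1 with 7.75-fold. Of 23 aminoacyl-tRNA synthetases 11 rose, 1 fell and 11 were not called (median 0.497, adjusted p = 2.51e-09), among them WARS1 8.21-fold and AARS1 4.3-fold, and 14 and 1 changed adjusted over the list alone. Amino acid transporters had 10 higher, 2 lower and 1 not called of 13, with the same counts adjusted over the list alone (median 1.72, adjusted p = 2.35e-08), and the cystine transporter pair SLC7A11 and SLC3A2 rose 9.26-fold and 8.84-fold. Ribosomal protein genes shifted by little, with 42 of 79 higher, 37 not called and 55 higher adjusted over the list alone (median 0.45, adjusted p = 3.56e-11), and RPS13 rose 1.73-fold. Their list lost its call with an adjusted p = 0.336 with an estimated correlation. The translation factors, with 12 of 40 higher, 28 not called and 13 higher adjusted over the list alone (median 0.172, adjusted p = 0.00134), did so as well, with an adjusted p = 0.185 with an estimated correlation, and their median was 0.268 without WT DMSO library 1 and 0.261 without WT Tm library 1. In that list EIF4EBP1, an ATF4 target that restrains cap-dependent translation, rose 5-fold.

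Proliferation genes fell. In the cell cycle list 27 of 36 were lower, 1 was higher and 8 were not called (median -0.718, adjusted p = 1.29e-12), and 29 were lower and 1 higher adjusted over the list alone. The replicative helicase genes MCM4 and MCM6 were 2.79-fold and 2.5-fold lower and the sliding clamp gene PCNA 2.29-fold, whereas CDC6, which loads that helicase, rose 2.24-fold. Cytosolic heat shock genes fell in 7 of 18 with 11 not called and 8 lower adjusted over the list alone (median -0.164, adjusted p = 0.00673), such as HSPB1 2.26-fold and HSPA8 1.79-fold. This call was lost with an adjusted p = 0.321 with an estimated correlation. Autophagy genes had 9 higher, 2 lower and 10 not called of 21 (median 0.333, adjusted p = 0.00467), or 12 and 4 adjusted over the list alone, with WIPI1 up 16.8-fold and MAP1LC3B 4.81-fold. NRF2 targets had 8 higher, 1 lower and 9 not called of 18 (median 0.395, adjusted p = 0.00186), or 10 and 2 adjusted over the list alone, and GCLC, the first enzyme of glutathione synthesis, rose 2.4-fold. Their list lost its call with an adjusted p = 0.0877 with an estimated correlation.

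Several lists held members that moved in opposite directions and were not called. Apoptosis genes had 4 higher and 2 lower of 21, also adjusted over the list alone (median 0.12, adjusted p = 0.344). The death receptor gene TNFRSF10B rose 2.23-fold (adjusted p = 8.93e-08), and APAF1, the core of the apoptosome, was 1.66-fold lower (adjusted p = 0.0109). Cholesterol synthesis had 5 higher and 8 lower of 24, or 5 and 11 adjusted over the list alone (median -0.252, adjusted p = 0.124), with HSD17B7 2.22-fold higher. Among 15 p53 targets the cell cycle inhibitor gene CDKN1A rose 4.31-fold, and SESN1, DDB2 and BTG2 were 2.11-fold, 2.13-fold and 2.47-fold lower, in both adjustments (median -0.268, adjusted p = 0.147). NF-kB targets had 2 higher and 5 lower of 14 in both adjustments, with CXCL2 4.63-fold higher and CXCL8 1.76-fold lower. Their median was 0.0532 and their mean 0.209, while the test leaned down (adjusted p = 0.578). The interferon response (6 higher and 2 lower of 30, or 8 and 2 adjusted over the list alone) had a median of -0.0264 and a mean of 0.252, and its test leaned up (adjusted p = 0.367). The remaining lists, with no call, were ribosome biogenesis (adjusted p = 0.216), secretory markers (0.162), mitochondrially encoded genes (0.413), neighbours of QRICH1 (0.168), immediate early genes (0.172), nuclear oxidative phosphorylation (0.11), glycolysis and hypoxia (0.216, with median -0.263 and mean 0.0167), and absorptive markers (0.948, with median 0.0868 and a test that leaned down).

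Tm against DMSO in QRICH1 KO asks the same of cells given the QRICH1 guide. The stress genes of the panel rose here too, and whether their response differed from that in WT is tested by the interaction. HSPA5 rose 14.6-fold (log2 3.87, SE 0.139, adjusted p = 1.16e-12), from 1130 ± 65.8 to 16500 ± 1340 CPM (SD, n = 3), HSP90B1 7.24-fold (log2 2.86, SE 0.111), DNAJB9 12.2-fold, SDF2L1 11.2-fold and HERPUD1 22.9-fold (log2 4.52, SE 0.125, adjusted p = 4.87e-14). DDIT3 rose 13.7-fold (log2 3.78, SE 0.173), TRIB3 13.8-fold, CHAC1 11.3-fold, ATF4 2.44-fold (adjusted p = 4.3e-07), ATF3 3.05-fold and XBP1 1.83-fold (adjusted p = 0.000579). AGR2 rose 26.3-fold (log2 4.71, SE 0.152), NUCB2 17.8-fold, NIBAN1 17.8-fold (27.3-fold without QRICH1 KO DMSO library 3), DDIT4 14.2-fold and SEC24D 13.6-fold. The largest decreases were of EDN1 with 3.09-fold (log2 -1.63, SE 0.215, adjusted p = 2.83e-05), the transcription factor GATA2 with 2.55-fold, FAM111B and UHRF1 with 2.37-fold each, BCAM with 2.23-fold and TONSL with 2.22-fold.

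By the edgeR test 1029 genes were higher and 739 lower with Tm in QRICH1 KO, of which 359 and 70 changed at least 2-fold. The libraries of the groups did not overlap in 1020 and 711 of them, and in 32.4% of all genes, against 10% by chance. The number lower fell to 452 without QRICH1 KO DMSO library 1, 395 without QRICH1 KO DMSO library 2, 445 without QRICH1 KO Tm library 2 and 407 without QRICH1 KO Tm library 3, and was 473 without both libraries 3, an alternative chosen after seeing the data. Of the genes called in WT, 875 were also higher in QRICH1 KO and 539 also lower, where independent lists would share 130 and 82.2, and no gene was called in opposite directions. The fold had the same sign in QRICH1 KO for 97.7% of the genes higher in WT and 96.9% of those lower. Across all genes tested the log2 responses had a Pearson correlation of 0.749 and a Spearman correlation of 0.661, with a slope of 0.781 by total least squares of QRICH1 KO on WT. Within the ER chaperone list the slope was 0.835. Such a slope leaves out a shift shared by the genes, so it does not give the share of the response kept. The summed log2 response of this list in QRICH1 KO was 0.77 of that in WT. The comparisons share no library, and genes are not independent replicates.

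**Figure D2:**
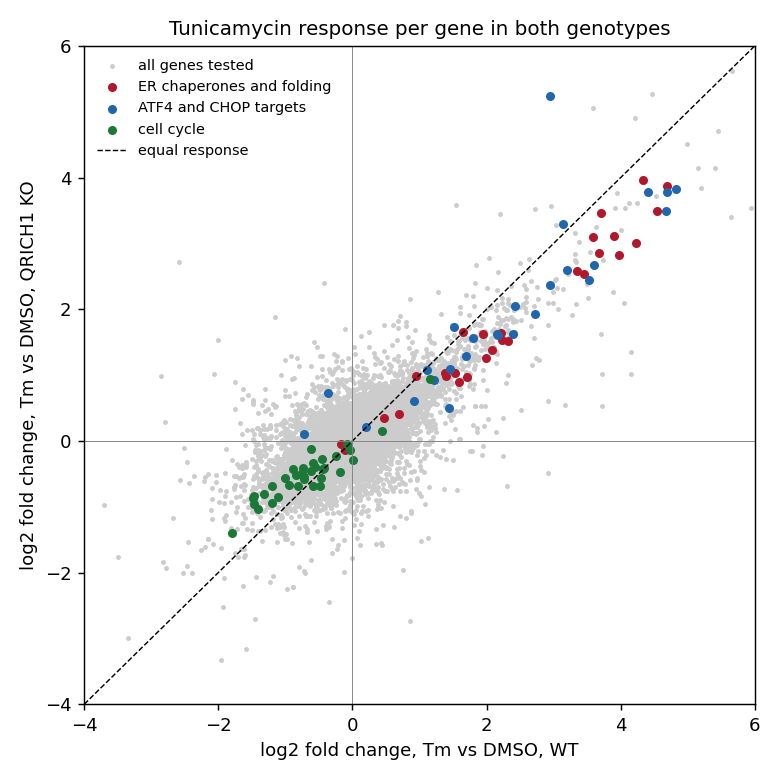
Log2 fold change with Tm in WT (x axis) against that in QRICH1 KO (y axis), 1 point per gene, for 11316 of the 11323 genes tested (7 lie outside the axes); red points are ER chaperones, blue ATF4 and CHOP targets, green cell cycle genes, grey all others, and the dashed line marks an equal response. The red points lie mostly below the dashed line on the right, with list medians of 2.15 in WT and 1.58 in QRICH1 KO.

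In QRICH1 KO 24 of 28 ER chaperones rose and 4 were not called (median 1.58, camera adjusted p = 3.26e-28), with 26 adjusted over the list alone. ERAD had 17 of 28 higher and 11 not called, or 18 higher and 1 lower adjusted over the list alone (median 0.728, adjusted p = 4.39e-12), with CRELD2 at 7.08-fold among the chaperones and SELENOS at 4.27-fold. ER translocation rose in 21 of 25, or 23 adjusted over the list alone (median 1.06, adjusted p = 3.81e-23), including SEC61A1 3.39-fold. N-glycosylation rose in 20 of 36, or 23 with 2 lower adjusted over the list alone (median 0.539, adjusted p = 1.4e-10), with PGM3 at 4.12-fold, and ER-Golgi transport in 35 of 42, or 38 adjusted over the list alone (median 0.957, adjusted p = 4.38e-27), with ARFGAP3 at 4.21-fold. The 7 transducers that rose of 12, also adjusted over the list alone (median 0.815, adjusted p = 3.53e-05), included ERN1, which encodes the sensor IRE1, at 3.42-fold. ATF4 and CHOP targets had 21 of 26 higher, or 22 adjusted over the list alone (median 1.68, adjusted p = 1e-25), with PSAT1 at 5.15-fold. Aminoacyl-tRNA synthetases had 11 of 23 higher, or 12 adjusted over the list alone (median 0.551, adjusted p = 8.6e-08), with WARS1 at 5.51-fold. Amino acid transporters had 10 of 13 higher in both adjustments (median 1.24, adjusted p = 1.71e-09), with SLC7A11 at 5.77-fold. In the cell cycle list 24 of 36 were lower and 1 higher, or 28 and 1 adjusted over the list alone (median -0.528, adjusted p = 4.76e-13), and MCM4 was 1.82-fold lower, PCNA 1.92-fold lower and CDC6 1.92-fold higher.

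Mitochondrially encoded genes, which code for respiratory chain subunits, rose in QRICH1 KO with Tm in 8 of 13, or 10 adjusted over the list alone (median 0.507, adjusted p = 5.8e-05), with MT-ND3 at 1.83-fold and MT-CO1 at 1.5-fold. Their call was lost with an adjusted p = 0.286 with an estimated correlation. Nuclear oxidative phosphorylation genes were higher in 8 of 48, or 15 adjusted over the list alone (median 0.206, adjusted p = 0.00752), with an adjusted p = 0.512 with an estimated correlation, 0.16 without QRICH1 KO DMSO library 3 and 0.057 (median 0.104) without QRICH1 KO Tm library 1. Ribosomal proteins were higher in 24 of 79, or 29 adjusted over the list alone (median 0.322, adjusted p = 2.58e-09), with an adjusted p = 0.459 with an estimated correlation, and RPS23 rose 2-fold. Translation factors were higher in 8 of 40, and also in 8 adjusted over the list alone (median 0.1, adjusted p = 0.00597), with an adjusted p = 0.251 with an estimated correlation and a median of 0.151 without QRICH1 KO DMSO library 1 and 0.152 without QRICH1 KO Tm library 1. Heat shock genes were lower in 7 of 18, or 8 adjusted over the list alone (median -0.257, adjusted p = 0.00021), with an adjusted p = 0.187 with an estimated correlation, and HSPH1 was 1.91-fold lower. NRF2 targets were higher in 8 of 18, or 9 adjusted over the list alone (median 0.327, adjusted p = 0.00104), with an adjusted p = 0.0746 with an estimated correlation. Autophagy had 7 higher and 1 lower of 21 in both adjustments (median 0.262, adjusted p = 0.00452), with WIPI1 at 11.6-fold.

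No call was made in QRICH1 KO for apoptosis (5 of 21 higher, adjusted p = 0.0764), in which TNFRSF10B rose 2.14-fold, or for p53 targets (adjusted p = 0.439), in which CDKN1A rose 3.24-fold. Cholesterol synthesis (0.245), NF-kB targets (0.49), the interferon response (0.864), absorptive (0.864) and secretory markers (0.267), neighbours of QRICH1 (0.499), immediate early genes (0.583), glycolysis and hypoxia (0.307) and ribosome biogenesis (0.864) also had no call. Median and mean differed in sign for cholesterol synthesis (-0.112 and 0.00863), NF-kB targets (-0.246 and 0.273), the interferon response (-0.00945 and 0.0335), glycolysis and hypoxia (-0.165 and 0.0416) and ribosome biogenesis (0.0155 and -0.00524).

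QRICH1 KO against WT under Tm asks which transcript levels depend on the QRICH1 guide during ER stress. ER folding genes stood lower in QRICH1 KO. HSPA5 was 1.69-fold lower (log2 -0.76, SE 0.124, adjusted p = 0.00484) and HSP90B1 1.71-fold lower (log2 -0.77, SE 0.104, adjusted p = 0.00193), with 16500 ± 1340 against 27900 ± 2630 CPM and 5100 ± 284 against 8720 ± 43.2 CPM (SD, n = 3). HERPUD1 was 1.49-fold lower (SE 0.107 on the log2 scale, adjusted p = 0.0118), with adjusted p = 0.0503 without WT Tm library 2 and 0.0584 without QRICH1 KO Tm library 3. SDF2L1 was 1.51-fold lower (adjusted p = 0.0278), a call that was lost with adjusted p = 0.138 without WT Tm library 2, 0.0514 without WT Tm library 3, and 0.0574, 0.115 and 0.112 without QRICH1 KO Tm library 1, 2 or 3. The genes of the ATF4 and CHOP branch in the panel were not called, with log2 fold changes of -0.20 for ATF4 (adjusted p = 0.505), -0.25 for DDIT3 (0.494), -0.40 for TRIB3 (0.267) and -0.26 for CHAC1 (0.699). DNAJB9 (-0.36) had an adjusted p = 0.167, against 0.0359 by DESeq2 and 0.0385 by voom. XBP1 (0.10, adjusted p = 0.848), ATF3 (-0.21, 0.805) and ASNS (0.09, 0.966) were not called.

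By the edgeR test 46 genes were higher and 86 lower in QRICH1 KO under Tm, 16 and 17 of them at least 2-fold. DESeq2 called 87 and 203, voom 92 and 165, and edgeR without a low-count filter 126 and 153. The libraries of the groups were fully separated in all 132 of the edgeR calls and in 18.5% of all genes tested, against 10% by chance. These counts rest on every library. Without WT Tm library 1, 2 or 3 they were 13, 19 and 29 higher and 49, 42 and 47 lower, and without QRICH1 KO Tm library 1, 2 or 3 they were 23, 21 and 30 higher and 47, 36 and 41 lower. Among the largest increases were HPGD, which degrades prostaglandins, and the cytidine deaminase gene APOBEC3C with 2.36-fold each, the protease inhibitor gene SERPINE2 with 2.24-fold (log2 1.17, SE 0.123, adjusted p = 0.000271), CLDN2 with 2.23-fold, the tubulin gene TUBA1A with 1.98-fold and the peptidylarginine deiminase gene PADI1 with 1.92-fold. Among the largest decreases were LAMB2, a laminin chain gene, with 3.28-fold (log2 -1.71, SE 0.289, adjusted p = 0.00519), SYTL1 with 2.56-fold, ITPRIP, which binds the inositol trisphosphate receptor, with 2.39-fold (log2 -1.26, SE 0.153, adjusted p = 0.000849), the glutaredoxin gene GLRX with 2.19-fold, PGM1 with 2.05-fold, ETHE1 with 2.03-fold and DBN1 with 2.01-fold. All of these genes kept their call without any 1 of the 6 libraries. Of the 52 called genes that the naming rule allows in this comparison, 24 did so, and the genes above come from these. COTL1, an actin-binding protein gene, had the largest increase by the rule with 4.95-fold (log2 2.31, SE 0.53, adjusted p = 0.0412), and lost its call with adjusted p = 0.159 and 0.16 without WT Tm library 1 or 2 and 0.11 and 0.14 without QRICH1 KO Tm library 1 or 2. Without WT Tm library 3 its fold was 8.25.

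**Figure D3:**
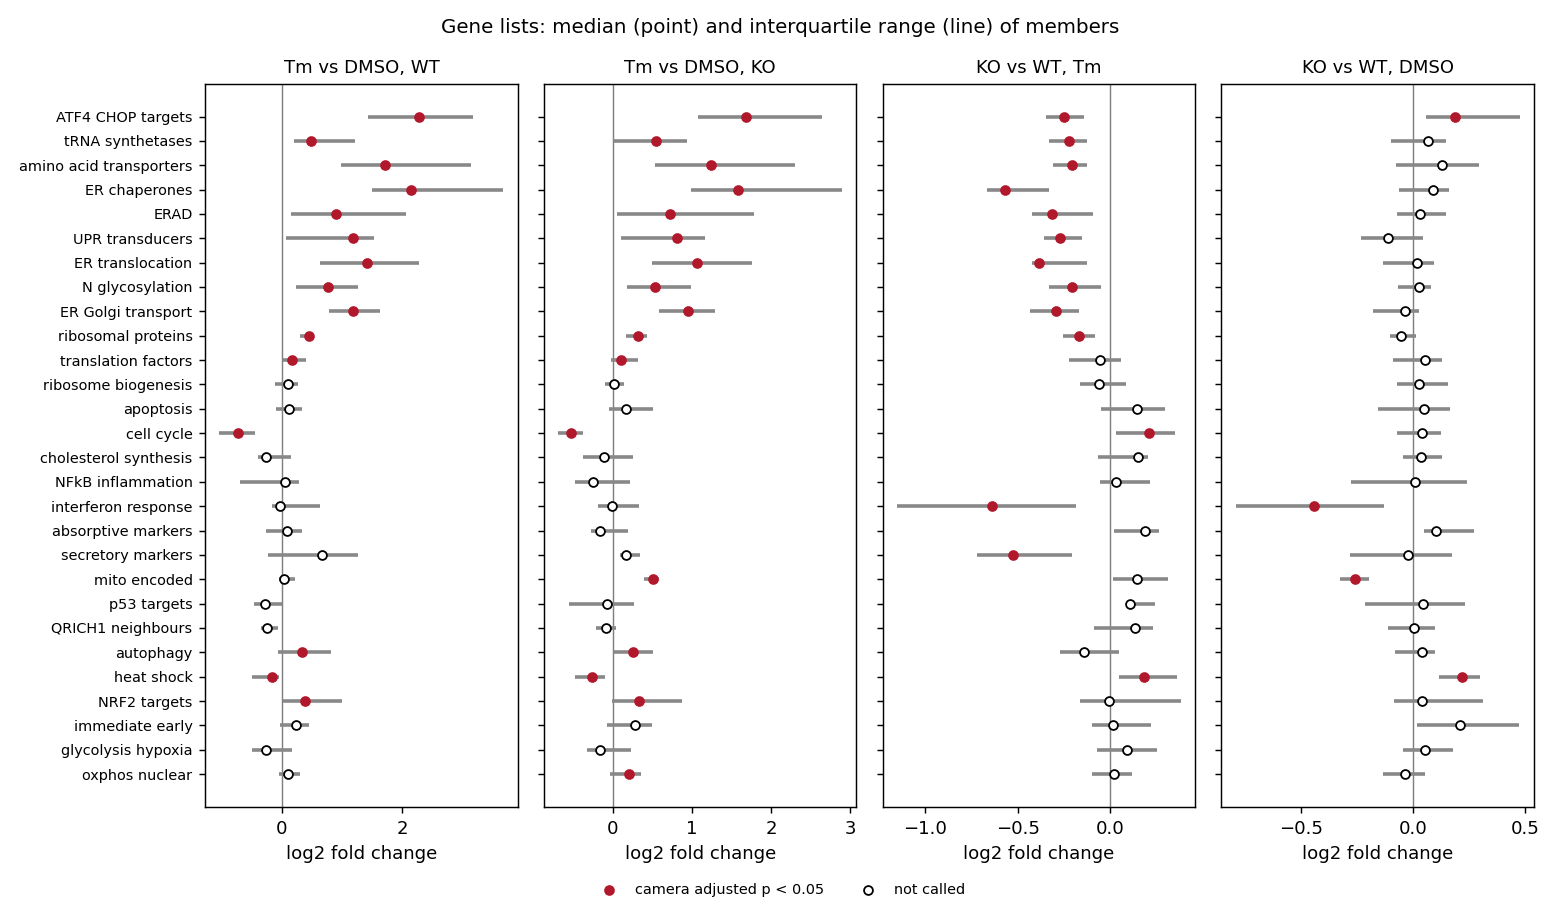
Median log2 fold change of each of 28 gene lists (points, x axis, with a different scale in each panel) and the interquartile range of its members (lines) in 4 comparisons; filled red points had a camera adjusted p under 0.05 and open points did not. The ER chaperone list has a median of 2.15 with Tm in WT, 1.58 with Tm in QRICH1 KO and -0.57 in QRICH1 KO against WT under Tm.

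The secretory pathway lists were lower in QRICH1 KO under Tm. Of 28 ER chaperones 9 were lower and 19 not called, with 19 lower adjusted over the list alone (median -0.57, camera adjusted p = 3.9e-15), for example PDIA4 and ERP44, both of the protein disulfide isomerase family, with 1.66-fold and 1.54-fold. ERAD had 5 of 28 lower, or 11 with 1 higher adjusted over the list alone (median -0.314, adjusted p = 1.99e-06), including OS9 with 1.61-fold and SELENOS with 1.55-fold. ER translocation had 5 of 25 lower, or 15 adjusted over the list alone (median -0.382, adjusted p = 5.97e-10), including TRAM1 with 1.65-fold. N-glycosylation had 2 of 36 lower, or 8 adjusted over the list alone (median -0.209, adjusted p = 5.97e-06), including OSTC with 1.53-fold. ER-Golgi transport had 9 of 42 lower, or 18 adjusted over the list alone (median -0.293, adjusted p = 5.3e-14), including the KDEL receptor gene KDELR1 with 1.57-fold. ATF4 and CHOP targets had 3 of 26 lower, or 6 adjusted over the list alone (median -0.252, adjusted p = 5.43e-05), and aminoacyl-tRNA synthetases 1 of 23, or 7 adjusted over the list alone (median -0.225, adjusted p = 4.77e-06). These 7 calls held with an estimated correlation. Amino acid transporters had none of 13 called, or 1 lower adjusted over the list alone (median -0.206, adjusted p = 0.0219), with an adjusted p = 0.0697 with an estimated correlation, 0.0531 without WT Tm library 2 and 0.0678 without QRICH1 KO Tm library 3. The 12 transducers had none called, or 2 lower adjusted over the list alone (median -0.269, adjusted p = 0.013), with an adjusted p = 0.0539 with an estimated correlation and 0.0503 without QRICH1 KO Tm library 3.

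Interferon response genes were lower in 6 of 30, or 15 adjusted over the list alone (median -0.639, adjusted p = 3.75e-11), a call that held with an estimated correlation. The antiviral genes OASL and IFIT1 were 3.27-fold and 2.02-fold lower (adjusted p = 0.0208 and 0.017). Single genes of this list were less stable than the list. OASL had adjusted p = 0.071 and 0.0871 without WT Tm library 1 or 2 and 0.0924 and 0.0877 without QRICH1 KO Tm library 2 or 3, and IFIT1 had 0.0699, 0.0748, 0.0646 and 0.0766 without the same libraries. Cell cycle genes were higher in 3 of 36, or 13 adjusted over the list alone (median 0.206, adjusted p = 5.97e-06), a call that held with an estimated correlation (adjusted p = 0.0319). MCM4 was 1.52-fold higher (log2 0.61, SE 0.101), and the S-phase transcription factor gene E2F1 2.01-fold (adjusted p = 0.00828), with adjusted p = 0.0565 without WT Tm library 1. Secretory epithelial markers had 2 of 8 lower in both adjustments (median -0.524, adjusted p = 0.0198). This call was lost with an adjusted p = 0.156 with an estimated correlation, 0.121 (median -0.347) without WT Tm library 2, 0.105 without QRICH1 KO Tm library 2 and 0.0503 without QRICH1 KO Tm library 3. The median was -0.336 without WT Tm library 3, and the member with the smallest p was AGR2 with 1.68-fold. Ribosomal proteins had none of 79 called in either adjustment (median -0.17, adjusted p = 5.43e-05), with an adjusted p = 0.543 with an estimated correlation and a median of -0.0153 (adjusted p = 0.543) without WT Tm library 2, -0.293 without WT Tm library 1 and -0.257 without QRICH1 KO Tm library 1. Heat shock genes had none of 18 called, or 6 higher adjusted over the list alone (median 0.182, adjusted p = 0.000982), with an adjusted p = 0.212 with an estimated correlation.

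No call was made under Tm between genotypes for translation factors (adjusted p = 0.12), ribosome biogenesis (0.375), apoptosis (0.215), cholesterol synthesis (0.12), NF-kB targets (0.387), absorptive markers (0.142), mitochondrially encoded genes (0.0854), p53 targets (0.12), autophagy (0.101), immediate early genes (0.705), glycolysis and hypoxia (0.12) and nuclear oxidative phosphorylation (0.917). NRF2 targets (adjusted p = 0.565) had a median of -0.00631 and a mean of 0.118. Neighbours of QRICH1 on chromosome 3 (0.384) had a median of 0.134 and a mean of -0.00526, and LAMB2 was the only 1 of 15 called.

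QRICH1 KO against WT under DMSO asks the same without added stress. Few genes were called by the edgeR test. SERPINE2 was 2.91-fold higher in QRICH1 KO (log2 1.54, SE 0.125, adjusted p = 4.42e-06), with 52.5 ± 1.14 against 18.1 ± 1.54 CPM (SD, n = 3), and PADI1 was 1.95-fold higher (adjusted p = 0.00429). ITPRIP was 3.12-fold lower (log2 -1.64, SE 0.152, adjusted p = 1.85e-05), with 12.9 ± 1.95 against 40.5 ± 5.05 CPM, the interferon-induced IFI27 was 2.39-fold lower (adjusted p = 0.0052) and ETHE1, a mitochondrial sulfur dioxygenase gene, 2.21-fold lower (adjusted p = 0.0052). These 5 genes kept their call without any 1 of the 6 libraries. No panel gene was called, with log2 fold changes of 0.06 for HSPA5 (adjusted p = 0.906) and 0.05 for HSP90B1 (0.918). TRIB3 had 0.51 (adjusted p = 0.345), and was called without a low-count filter (0.0165) and without WT DMSO library 3 (0.0363).

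By the edgeR test 2 genes were higher and 9 lower in QRICH1 KO under DMSO, against 23 and 36 by DESeq2, 31 and 36 by voom, and 76 and 62 by edgeR without a low-count filter. The libraries of the groups were fully separated in all 11 and in 13.5% of all genes tested, against 10% by chance. Without QRICH1 KO DMSO library 3, 1 of the libraries with more genes detected, 20 were higher, and without WT DMSO library 2, 3 were lower. Without both QRICH1 KO libraries 3, an alternative chosen after seeing the data, 39 were higher and 19 lower. LAMB2 was 2.9-fold lower (adjusted p = 0.0252), a call lost with 0.0826 and 0.178 without WT DMSO library 1 or 2 and 0.0844 and 0.17 without QRICH1 KO DMSO library 1 or 2. PGM1 (log2 -0.94, adjusted p = 0.0296) lost its call with 0.0826 and 0.191 without WT DMSO library 1 or 2 and 0.0807 and 0.0539 without QRICH1 KO DMSO library 2 or 3. The receptor kinase gene AXL (-0.86, adjusted p = 0.0299) lost it with 0.0537, 0.107 and 0.124 without WT DMSO library 1, 2 or 3 and 0.202 without QRICH1 KO DMSO library 2. OAS3 (-0.81, adjusted p = 0.0118) lost it with 0.0529 and 0.0882 without WT DMSO library 1 or 2. In the fit to only the 6 libraries compared, the adjusted p was 0.0526 for PGM1, 0.153 for AXL and 0.0526 for OAS3. CCDC106 (-2.22, adjusted p = 0.0127) and INPPL1 (-1.79, adjusted p = 0.0252) complete the 9 and were chosen after their values were seen. CCDC106 lost its call with 0.109 without WT DMSO library 2, 0.0555 without QRICH1 KO DMSO library 1 and 0.061 in the fit to only the 6 libraries. INPPL1 lost it with 0.183 without WT DMSO library 2, 0.165 and 0.0509 without QRICH1 KO DMSO library 2 or 3, and 0.0838 in that fit. Both genes that were higher and 8 of the 9 that were lower were also called under Tm. The exception was INPPL1 with adjusted p = 0.151 there.

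Of 28 lists 4 were called under DMSO, and none of these calls held with an estimated correlation. Interferon response genes were lower in 2 of 30, or 9 adjusted over the list alone (median -0.444, camera adjusted p = 7.38e-09), with an adjusted p = 0.0929 with an estimated correlation. Heat shock genes had none of 18 called, or 2 higher adjusted over the list alone (median 0.219, adjusted p = 6.42e-05), with an adjusted p = 0.356 with an estimated correlation. ATF4 and CHOP targets had none of 26 called, or 2 higher adjusted over the list alone (median 0.189, adjusted p = 0.00262), with an adjusted p = 0.0929 with an estimated correlation. Mitochondrially encoded genes had none of 13 called in either adjustment (median -0.261, adjusted p = 0.00177), with an adjusted p = 0.659 with an estimated correlation, and 0.114 (median -0.137) without WT DMSO library 3 and 0.189 (median -0.135) without QRICH1 KO DMSO library 2. ER chaperones were not called (median 0.0911, adjusted p = 0.192), nor were ERAD (0.493), ER translocation (0.56, with median 0.0165 and mean -0.0298), N-glycosylation (0.948), ER-Golgi transport (0.127) or the cell cycle (0.493). Among the other uncalled lists, p53 targets, neighbours of QRICH1 and autophagy had a positive median and a test that leaned down (adjusted p = 0.948, 0.56 and 0.948). Across all genes the QRICH1 KO effect under Tm had a Pearson correlation of 0.245 and a Spearman correlation of 0.214 with that under DMSO.

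The interaction asks whether the Tm response differed between the genotypes. No single gene was called by the edgeR test, with 774 genes at an unadjusted p under 0.05 and a smallest adjusted p = 0.0721. DESeq2 called 9 genes higher and 37 lower, and voom 1 higher and 9 lower, of which 9 were called by both. Without WT DMSO library 3 the edgeR test called 4 genes lower, among them TRIB3 (log2 -1.19, adjusted p = 0.0293), and without a low-count filter it called 12 higher and 32 lower. The response of HSPA5 was smaller in QRICH1 KO by a log2 difference of -0.82 (SE 0.176, adjusted p = 0.142, with 0.000155 by DESeq2 and 0.0356 by voom) and that of HSP90B1 by -0.82 (SE 0.146, adjusted p = 0.0721, with 1.02e-08 by DESeq2 and 0.0155 by voom). Without a low-count filter both were called (0.00238). The smallest adjusted p of the edgeR test for the interaction was 8.62e-06 in that fit, against 0.0721 with the filter. Calls made only without the filter show a dependence on it and are not taken as support. SDF2L1 had -1.06 (SE 0.198, adjusted p = 0.0875, with 0.000849 by DESeq2, 0.116 by voom and 0.000498 without a filter) and TRIB3 -0.91 (0.266, with 0.0186, 0.059 and 0.000964 in that order). The other panel genes were not called, with DDIT3 at -0.63 (0.651), HERPUD1 -0.47 (0.456), DNAJB9 -0.51 (0.521), ATF4 -0.40 (0.69), ATF3 -0.57 (0.851), CHAC1 -1.18 (0.538) and XBP1 -0.24 (0.874). ASNS (adjusted p = 0.89) lay too near the detection limit for a value. The list members CRELD2 (-1.15, SE 0.191), SELENOS (-0.82, SE 0.149) and SESN2 (-1.09, SE 0.192) were among those that shared the smallest adjusted p of 0.0721. DESeq2 called all of these, and voom all but SESN2 (adjusted p = 0.116).

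As groups, 10 lists differed in their response by camera. The response was smaller in QRICH1 KO for ER chaperones (median -0.633, adjusted p = 1.51e-15, 26 of 28 members negative), ATF4 and CHOP targets (-0.469, 1.51e-08, 20 of 26), amino acid transporters (-0.394, 0.00124, 11 of 13), ER translocation (-0.279, 5.17e-07, 22 of 25), aminoacyl-tRNA synthetases (-0.262, 1.26e-05, 19 of 23), ERAD (-0.254, 6.01e-07, 24 of 28), N-glycosylation (-0.247, 4.11e-05, 29 of 36) and ER-Golgi transport (-0.234, 1e-07, 38 of 42). These 8 calls held with an estimated correlation, with adjusted p-values from 0.00343 (ER chaperones) to 0.0394 (aminoacyl-tRNA synthetases). No member was called over all genes, and adjusted over the list alone 15, 8, 5, 8, 3, 8, 0 and 2 members, in the order of the lists above, were lower. For aminoacyl-tRNA synthetases the median response itself was not smaller, with 0.551 in QRICH1 KO and 0.497 in WT, while the mean was (0.597 and 0.818). Cell cycle genes, which fell with Tm in both genotypes, had a higher interaction value (median 0.191, adjusted p = 0.000635, 28 of 36 positive), with an adjusted p = 0.0999 with an estimated correlation. Mitochondrially encoded genes did too (median 0.392, adjusted p = 3.25e-05, 13 of 13 positive), with an adjusted p = 0.308 with an estimated correlation and a median of 0.258 without QRICH1 KO DMSO library 2. Adjusted over the list alone, 1 member of each was higher. The nearest uncalled lists were ribosomal proteins (-0.133, adjusted p = 0.0803) and translation factors (-0.0713, 0.0876), and the transducers (-0.0839, 0.175) and the interferon response (-0.0174, 0.327) were not called. Absorptive markers (0.947) had a negative median and a test that leaned up.

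Some of the genes named share exons with a neighbour, so their levels are uncertain, since the libraries do not mark the strand. DDIT3 shares 39.6% of its exonic length with MARS, DDIT4 41.2% with its antisense gene, WIPI1 28.1% with ARSG, SRPRB 21.1% with an antisense gene, ETHE1 14.8% with ZNF575, PGM3 14.8% with DOP1A, TUBA1A 14.3% with TUBA1C and OS9 13.5% with an antisense gene. ASNS shares 44.6% with a noncoding transcript on its own strand, so its level is uncertain whether or not strand is marked. Reads of near-identical copies, such as those of ribosomal protein, tubulin and trypsinogen genes or of mitochondrial genes and their nuclear copies, are uncertain in the same way.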

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

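The comparison with other induced genes and the count of splits with an estimated correlation were chosen only after the results were seen. The results below were singled out because the Tm response of a gene list differed between WT and QRICH1 KO in the test of the interaction.

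The Tm response was smaller in QRICH1 KO for 8 lists, with median interaction values (log2) of -0.633 for ER chaperones, -0.469 for ATF4 and CHOP targets, -0.394 for amino acid transporters, -0.279 for ER translocation, -0.262 for aminoacyl-tRNA synthetases, -0.254 for ERAD, -0.247 for N-glycosylation and -0.234 for ER-Golgi transport. The median response of aminoacyl-tRNA synthetases itself was 0.497 in WT and 0.551 in QRICH1 KO, so only its mean (0.818 and 0.597) and its member-wise differences were smaller. These 8 calls held with an estimated correlation. Between genotypes, ATF4 and CHOP targets had a median of -0.252 under Tm and 0.189 under DMSO. Their DMSO call was lost with adjusted p = 0.0929 with an estimated correlation. Their interaction may thus hold a higher DMSO level in QRICH1 KO besides a lower level under Tm. ER chaperones had -0.57 under Tm and 0.0911 under DMSO, with no DMSO call. Cell cycle genes had a median interaction of 0.191, a call lost with adjusted p = 0.0999 with an estimated correlation. Mitochondrially encoded genes had a median of 0.392, a call lost with adjusted p = 0.308 with an estimated correlation and 0.223 by fry, and a median that was 0.258 without QRICH1 KO DMSO library 2. Between genotypes their median was 0.144 under Tm, with no call, and -0.261 under DMSO. The DMSO call was lost with adjusted p = 0.659 with an estimated correlation and 0.335 by fry, and the DMSO median was -0.135 without QRICH1 KO DMSO library 2 and -0.137 without WT DMSO library 3.

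The first pattern is the smaller response of the 221 members of the 8 lists. A GC content or gene length bias is argued against. Removing such a trend from each library took the members' median from -0.307 to -0.332 (bootstrap SE 0.0149) and left 8 of 8 lists called. Thinning all libraries to the smallest total gave -0.328 (SE 0.024) with 8 of 8 called. Thinning keeps the expected CPM of a gene, so it could hardly have removed the pattern and does not decide on library depth. An evenly weaker response of all genes that Tm induces may account for most of the lists. The 177 induced members (median -0.359) lay at the 6.62 percentile of 10000 sets of other genes matched on their mean response (median -0.323). These sets came from any induced gene outside the lists, and the lists leave out some ER genes, such as SERP1 and HM13. A weaker response of all induced genes thus cannot be told apart here from one of ER stress genes alone. For ER chaperones the same comparison gave the 0.01 percentile, the smallest these sets can give (-0.691 against -0.427). For ERAD it gave the 0.14 percentile (-0.47 against -0.283). The medians of these 2 lists thus lay below those of most matched sets. The sets draw genes singly, and cover neither co-regulation within a list nor the spread of the libraries. All 8 lists were also chosen for low values in this same interaction, so an even weakening is not excluded for these 2. An effect of QRICH1 on the whole response, a smaller effective dose of Tm in 1 line and an effect on ER chaperone genes beyond either stay open, and the first 2 cannot be separated with these groups.

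The other lists lay between the 7.06 percentile (ATF4 and CHOP targets) and the 98.1 percentile (ER-Golgi transport) of their matched sets, and cell cycle genes at 99. The 1583 induced genes outside the lists had a median interaction of -0.144, and all 1857 repressed genes 0.134. Their median log2 responses, averaged over both genotypes, were 0.57 and -0.507. That of the 177 induced members was 1.39, so their median interaction of -0.359 belongs to a larger response.

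Other splits of the 12 libraries were drawn within each treatment, 100 of 200 possible. The real groups gave 10 lists called in the interaction and the highest other split 14, and 7 of the 100 splits, the real one included, called at least 10, so chance is not excluded for this count. These 7 all keep the Tm libraries grouped by genotype, and with the Tm libraries regrouped the highest was 8. With an estimated correlation the real groups gave 8 lists and the highest other split 7, so that 1 of the 100 splits, the real one, reached the real count. The next split differs by 1 list, but it keeps the Tm libraries grouped by genotype and so holds the real contrast under Tm. With the Tm libraries regrouped, each split drawn gave 0 lists. Such splits mix the genotypes on each side, which widens the spread, so they cannot decide on chance. The count with an estimated correlation was chosen after the planned one had not excluded chance, so it does not settle the question. For genes the real count was 0 and the highest other 1. No split can give fewer than 0, so that 100 of 100 splits gave at least as many as the real groups says nothing about chance.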

How the results depend on the processing

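Leaving out both QRICH1 KO libraries 3 was chosen only after the data were seen, and so was keeping the genes tested fixed when libraries are left out. No called gene named changed direction under any alternative run for it, and no called list under those run for lists. The lists were not run with DESeq2, voom, no filter or the fit to 6 libraries. RLE scaling and the stricter filter kept all 60 list calls, and RLE kept the calls of all 333 named results. DESeq2 kept 324 named results and added 5 calls, voom kept 326, added 3 and lost 4, no filter kept 324, added 5 and lost 4, and the fit to only the 6 libraries compared kept 310 and lost 10. Leaving out 1 library lost 204 calls of named genes and added 2, and lost 11 of 420 list calls. An estimated correlation lost 21 of the 60 list calls and fry 6. Without both QRICH1 KO libraries 3, 18 named calls and 4 list calls were lost.

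The counts depend most on the filter, the test and single libraries in the comparisons with few calls, and the cause was not tested. With no filter the smallest adjusted p of the edgeR test was 2.88e-290 for Tm in WT, against 1.31e-14 with the filter. The counts with no filter are therefore not taken as support. QRICH1 KO against WT under Tm had 126 higher and 153 lower with no filter, 87 and 203 by DESeq2, and 92 and 165 by voom. Under DMSO it had 76 and 62 with no filter, 23 and 36 by DESeq2, 31 and 36 by voom, and 4 lower in the fit to the 6 libraries. The interaction had 12 and 32 with no filter, 9 and 37 by DESeq2, and 1 and 9 by voom. Without both QRICH1 KO libraries 3, 473 genes were lower with Tm in QRICH1 KO, and 39 were higher and 19 lower in QRICH1 KO under DMSO. With an estimated correlation 11 lists were called for Tm in QRICH1 KO, 9 for QRICH1 KO against WT under Tm and 0 under DMSO, where fry called 2. Over genes past the stricter filter the correlation of the Tm responses was 0.869, as fewer low genes enter.

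Leaving out each library in turn gave 1121 to 1325 genes higher and 908 to 1130 lower with Tm in WT, 725 to 991 and 395 to 781 with Tm in QRICH1 KO, 13 to 30 and 36 to 49 in QRICH1 KO under Tm, 2 to 20 and 3 to 12 under DMSO, and 0 to 0 and 0 to 4 in the interaction. Lists called ranged over 15 to 16, 16 to 18, 11 to 16, 3 to 6 and 10 to 13 in the same order. The correlation of the Tm responses was 0.695 to 0.738 and that of the QRICH1 KO effects 0.17 to 0.276. Fewer libraries enter each of these fits.

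The replicate number did not pair the samples across all groups. Deviations correlated above 0.1 in 6 of 18 same-number pairs (from -0.186 to 0.265), and 5 of 12 libraries correlated best with their own number. Within QRICH1 KO, the DMSO and Tm libraries had 0.213 for number 1, 0.002 for number 2 and 0.265 for number 3. Pairs of number 1 with number 3 had -0.237 and -0.239 there. A pairing within QRICH1 KO is thus not excluded, and the main model ignores it. With the number as a block, 1500 genes were higher and 1323 lower with Tm in WT, 1086 and 802 with Tm in QRICH1 KO, 58 and 103 in QRICH1 KO under Tm, 4 and 13 under DMSO, and 0 and 0 in the interaction, and all 60 list calls were kept. Depth limits genes of few counts, since 3 counts are 0.438 CPM in the smallest library, and the simulated interaction recovered 1.5% of 1.5-fold changes.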

Other observations

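The tests of a lost chromosome segment, of a single library and of genes matched in GC content and length were chosen only after the results were seen, and so were the genes outside the named lists below.

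Among the genes that DESeq2 called in the interaction, 27 of 46 belonged to the 8 lists with a smaller response in QRICH1 KO. These lists held 221 of the 11323 genes tested by edgeR. They were chosen for low values in this same interaction, so the overlap is not separate support. Outside every list, SERP1, which stabilises the translocon, had an interaction log2 value of -0.73 by edgeR (adjusted p = 0.0986, with 6.59e-05 by DESeq2 and 0.0356 by voom), and HM13, which encodes signal peptide peptidase, -0.77 (0.0986, with 6.59e-05 and 0.0392). Genes with a positive value included the glutamine synthetase gene GLUL at 0.69 (0.192, with 0.00437 by DESeq2 and 0.079 by voom), the coenzyme A synthesis gene PANK3 at 0.92 (0.127, with 0.00504 and 0.059), and SOSTDC1 at 0.96 (0.226, with 0.024 and 0.166), which was 3.76-fold lower with Tm in WT.

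Among lists that were not called, glycolysis and hypoxia had 3 higher, 7 lower and 17 not called of 27 with Tm in WT (median -0.263), and apoptosis 4 higher, 2 lower and 15 not called of 21 (median 0.12). Single members of them rose in both genotypes by the edgeR test. The angiogenic factor gene VEGFA rose 3.25-fold in WT and 4.65-fold in QRICH1 KO, the BH3-only gene PMAIP1 2.34-fold and 2.06-fold, the inflammatory caspase gene CASP4 1.58-fold and 1.46-fold, and the glucose transporter gene SLC2A1 1.63-fold and 1.32-fold. The glycolytic gene LDHA was 1.59-fold lower in WT.

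The second pattern is the lower LAMB2 in QRICH1 KO, by -1.71 under Tm and -1.54 under DMSO (log2). LAMB2 (chromosome 3:49121114-49133118, hg38) lies close to QRICH1, and a guide that removed the segment between them could lower it. The genes between, QARS1 (49095932-49105135) and USP19 (49108046-49120938), argue against a lost segment as the cause, since the lowest log2 value less 2 SE over both genes and treatments was -0.374. A local edit at LAMB2, an effect of QRICH1 on it and a difference between the lines that arose apart from QRICH1 stay open and were not tested.

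The third pattern is the lower interferon response list in QRICH1 KO, with medians of -0.639 under Tm and -0.444 under DMSO, where the call was lost with adjusted p = 0.0929 with an estimated correlation. Removing a GC content and length trend left the list called in both treatments at the preset correlation, with -0.482 (SE 0.133) under DMSO and -0.629 (SE 0.154) under Tm, though the margin set in advance, to keep more than 75% of the value by more than its SE, was missed under Tm. Against 10000 sets of genes matched in GC content and length the list lay at the 0.01 percentile in both treatments, the smallest these sets can give (lowest sets -0.21 and -0.142), so the tables argue against such a bias as the whole cause. A single library is argued against as well, since the median nearest to 0 without any 1 library was -0.338 and the call at the preset correlation was kept in 6 of 6 fits of each treatment. An effect of QRICH1 and another difference between the guide lines, such as their response to transduction, may each account for it and cannot be told apart, because guide and line coincide in these groups.

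For the comparisons of 3 libraries against 3, the 10 splits are too few for a share under 0.05. The real groups gave 2690 genes called for Tm in WT (highest other split 0), 1768 for Tm in QRICH1 KO (0), 132 for QRICH1 KO against WT under Tm (0) and 11 under DMSO (2). Lists called were 15 (highest other 15), 17 (17), 14 (9) and 4 (5) in the same order, and the splits with at least as many, the real one included, were 3, 2, 1 and 3. Each other split sets 2 libraries of 1 group with 1 of the other on each side. Part of any real difference therefore stays in its contrast, and the rest widens its spread. Neither the gene counts nor the list counts of these splits can thus decide on chance.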
